A study of Tribolium castaneum with 60 samples.

How the data were processed

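RNA sequencing of whole Tribolium castaneum larvae was analysed in 60 libraries. Each library came from a pool of 20 larvae, shock frozen 6 h after priming, per the labels. The libraries are 15 selection lines times 4 priming treatments. There were 6 lines selected for specific immunity, 6 lines selected for unspecific immunity and 3 untreated control lines. The treatments were a naive control and priming with heat-killed bacteria that the labels call Btt, Bt1 and Pf. Each line gave 1 library per treatment, so a library of one line pairs with the other 3 of that line. The names of the bacteria are not spelled out, and neither the priming route nor a wounded control is given in the sources used here.

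RNA was extracted with the mirVana kit and libraries were made with the TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark strand. FastQC, Trimmomatic 0.36, STAR 2.5.3, Cufflinks 2.2.1 and HTSeq 0.7.2 were named without their roles, per the submitters' processing notes. The genome build behind the alignment is not given in the sources used here. The deposited table holds raw read counts per gene and library, whole numbers with no normalization, for 14489 genes. The deposited gene table gives base positions (start and end) of each gene on RefSeq sequence records whose build it does not name, so no positions are printed. Gene symbols came from the supplied reference table of assembly icTriCast1.1, used for names only. It holds 12305 of the gene IDs (84.9%) and gives 4457 genes a symbol; the others keep their LOC identifiers. No genome sequence was used here, so near-identical gene copies were not compared. Of the 332 genes chosen for naming, 106 overlap another gene in position, as do 9 of the 32 among them with a call, listed where they appear.

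Column totals ran from 8.49 to 14.22 M counts, with a mean of 10.64 ± 1.44 M (SD, n = 60). At these totals, 1 CPM (a count scaled by the total of its library) is about 10 counts. None of the 132 pairs of libraries within a group was identical: the chi-square of their difference was 27.5 to 230.1 per degree of freedom over genes with at least 20 counts, where 2 draws from the same library give about 1.

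Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 11459 for the 12 groups of regime and treatment and 12101 for the 15 sums per line. Libraries were scaled with TMM factors, and dispersions and quasi-likelihood F tests used robust estimation. The biological coefficient of variation was 0.261 and the median prior degrees of freedom were 2.42. P-values were adjusted by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Where counts at an unadjusted p under 0.05 are given, a share of 0.05 of the genes tested would pass if none differed. Standard errors (SE) of log2 fold changes were taken from the F statistic. Priming was tested as primed minus naive, averaged over the 3 regimes with equal weight and within each regime. The bacteria were compared with each other, averaged and as a joint test within each regime. Regimes were compared with the counts of the 4 libraries of a line summed, so that the line was the unit, and in the naive libraries alone. Differences in response between regimes were joint tests of the interaction terms. These made 27 comparisons.

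Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and at least 5 tested members. An estimated correlation and fry were run beside it. Camera compares the mean t statistic of a list with that of the other genes. Lists said to rank higher or lower differ in that mean, which a single gene can carry. The 23 list topics were fixed before the data were examined. Their product-name patterns matched few genes, because the tables carry symbols rather than product names. Lists of symbols for 22 of the topics were therefore written after the gene tables were seen and before any count was tested; transposable elements matched none. Such lists can miss family members that carry only a LOC identifier, so a list does not stand for its whole family. Lists of fewer than 5 tested genes were described gene by gene. Values in the text are CPM with TMM scaling unless named otherwise, with the SD over lines.

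Genes were named by a rule fixed before the data were examined. It takes genes with a symbol and a mean of at least 1 CPM in 1 group. In averaged comparisons and sums per line it takes the 8 largest rises and 8 largest falls among called genes that moved the same way in at least 80% of lines, and in other comparisons the 3 largest of each. It adds up to 4 genes per list by smallest p, in averaged comparisons and sums per line, and the antimicrobial peptides Def, cec2 and DptB everywhere. Genes with a LOC identifier fall outside the rule and were chosen after their values were seen.

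Lines were checked as pairs before the fits were compared. The mean correlation of deviations from group means between libraries of the same line was 0.269 in specific, 0.431 in unspecific and 0.316 in control lines, against -0.0531, -0.0860 and -0.158 between lines of the same regime. Deviations cancel within each group, so the negative values follow from the positive ones and add no separate support. A library was closest to its own line in 22 of 24, 23 of 24 and 12 of 12 cases. Libraries with the same number in different regimes share the number only (mean r of 0.0344 against -0.00645). The fit with the line as a block, fixed in advance as the alternative, is therefore a paired analysis by design, and its counts stand beside the main ones where they differ by over 1.5 times.

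Other alternatives were DESeq2 1.42.0, RLE factors, no filter, a stricter filter (5 CPM in 3 libraries), fits to only the groups compared, limma-voom with the line as a random effect for regimes, and each line left out in turn. Dropping the 3 libraries more than 3 median absolute deviations (MAD) from the median of the first principal component was chosen after seeing the data. Principal components used log2 CPM with a prior count of 2. Other splits of the libraries numbered at most 100 per result. Random lists numbered 10000 and permutations 100000, all with fixed seeds.

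The tests were checked on simulated counts with 200 changed genes. For Btt against naive averaged over regimes, 11459 genes were simulated, and the fit recovered 81.5%, 86.6% and 100% of genes changed 1.5, 2 and 4 times, with 4.32% false calls. For Btt against naive in control lines it recovered 38.5%, 64.2% and 92.4%, with 3.01% false calls. For the sums of unspecific against control lines, 12101 genes were simulated, and 53.7%, 74.6% and 93.9% were recovered, with 5.13% false calls. For the response of specific against control lines, 28.4%, 62.7% and 81.8% were recovered, with 5.74% false calls. Simulated libraries carried no differences between lines. In camera, 4 of 100 random lists passed an unadjusted p of 0.05. Genes were simulated independently of each other, so this share says nothing about lists of correlated genes. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.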

Results

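Gene expression was measured by RNA sequencing in whole larvae of Tribolium castaneum, the red flour beetle, after experimental evolution. The series crosses 3 selection regimes with 4 priming conditions, and asks how larvae of each regime respond to priming. Priming is an exposure to heat-killed bacteria, and naive larvae were left unprimed. Each of the 12 groups held 1 library per line: 6 for specific immunity lines, 6 for unspecific immunity lines and 3 for untreated control lines. Total counts per library ran from 8.49 to 14.22 M (M, mega). Within specific lines they ran from 9.16 to 14.07 M in naive larvae, from 9.49 to 12.86 after Btt, from 8.67 to 13.88 after Bt1 and from 8.75 to 12.06 after Pf. In unspecific lines the ranges were 8.49 to 11.59, 8.59 to 14.22, 9.48 to 11.97 and 8.81 to 12.71 M in the same order. Control lines had 9.65 to 11.84, 8.78 to 11.19, 10.97 to 12.89 and 9.82 to 11.58 M.

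Transferrin and antimicrobial peptide transcripts separated primed from naive larvae in every line or nearly so. Tsf1, the iron-binding transferrin of insect hemolymph, averaged 143.8 ± 68.01 CPM in naive larvae (SD, n = 15 lines). It reached 1854 ± 686 CPM after Btt, 2310 ± 806 after Bt1 and 1783 ± 672 after Pf. DptB, a peptide of the diptericin family, went from 7.19 ± 4.60 CPM to 31.1 ± 18.8, 46.5 ± 34.9 and 68.2 ± 47.7 CPM. The cecropin cec2 went from 1.27 ± 0.726 CPM to 5.22 ± 3.12, 4.88 ± 2.22 and 4.76 ± 2.89 CPM. Def, a defensin, was scarce throughout, at 0.623 ± 0.967 CPM in naive larvae and 2.10 ± 2.17, 2.03 ± 1.51 and 3.72 ± 1.44 CPM after priming. The 3 naive control libraries held only 0, 1 and 2 counts of Def, so no fold change is given for it within control lines. Its averages over the 3 regimes include those lines with equal weight, and lie above its values within specific and unspecific lines (1.51 and 1.79 after Btt, 1.63 and 1.26 after Bt1, 2.22 and 2.23 after Pf). DptB lies wholly inside spri, a gene on the other strand, and the libraries do not mark strand. Counts of spri itself were 113 ± 14.6 CPM in naive larvae and 113 ± 13.9, 107 ± 11.2 and 114.7 ± 9.745 CPM after Btt, Bt1 and Pf.

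**Figure D1:**
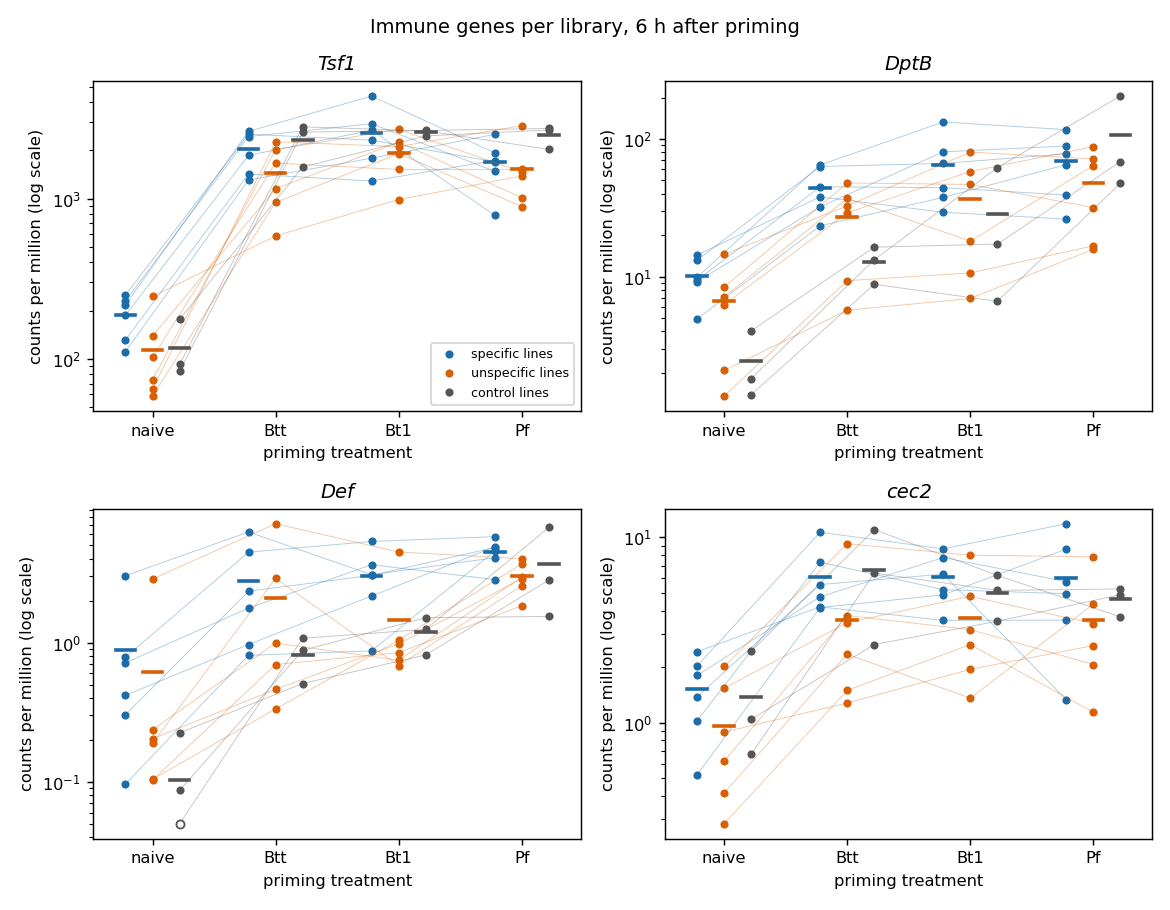
CPM (log axis) of Tsf1, DptB, Def and cec2 in each of the 60 libraries by priming treatment. Points are libraries, thin lines join the 4 libraries of a line, bars are group means, and open points drawn at 0.05 mark libraries with a count of 0. Mean Tsf1 was 187.3, 113.6 and 117.2 CPM in naive specific, unspecific and control lines and 1440 CPM or more in every primed group.

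Priming with Btt raised 110 genes and lowered 10 of 11459 when averaged over the 3 regimes. Tsf1 rose by a log2 fold change of 3.80 ± 0.26 (SE; adjusted p = 4.9e-16, higher in 15 of 15 lines), DptB by 2.19 ± 0.41 (adjusted p = 3.5e-04, 15 of 15) and cec2 by 2.04 ± 0.33 (adjusted p = 3.1e-05, 15 of 15). Def stood at 2.09 ± 0.57 and missed the threshold (adjusted p = 0.055, 15 of 15), which it passed with the line as a block (adjusted p = 0.0031). The other genes with a symbol that passed rose less, while some without one rose by more than DptB, LOC656629 by 3.03. The protease inhibitor Serpin5 rose by 0.71, Gnbp2, of the family of glucan-binding recognition proteins, by 0.60, the citrate transporter Indy by 0.77, the phospholipase sPLA2C by 0.74, the chemosensory protein Csp10 by 0.68, the chitinase-like growth factor Idgf4 by 0.49 and Ttc26 by 0.92. The named genes that fell moved little. They were the GTPase Ran at -0.24, the mitochondrial elongation factors mEFG1 at -0.23 and mEFTu1 at -0.20, the ribosome maturation factor Tsr1 at -0.19, the mitochondrial ribosomal protein mRpL44 at -0.14, the initiation factor subunit eIF3l at -0.12, and Al at -0.39. Among the falls, eIF3l, mRpL44 and mEFTu1 overlap another gene in position. The fit with the line as a block passed 376 genes (250 higher, 126 lower), including all 120.

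The gene lists gave the following picture for Btt averaged over regimes. Antimicrobial peptides rose in 2 of 3 genes over all genes tested and in 3 of 3 adjusted over the list alone. Iron and storage proteins ranked higher than other genes in camera, with 11 of 14 above 0 and 1 called, Tsf1 (adjusted p = 0.0014, adjusted p = 0.19 with an estimated correlation); adjusted over the list alone, 4 rose, among them the ferritin subunits Fer1HCH at 0.19 and Fer2LCH at 0.20 (adjusted p = 0.084 and 0.073 over all genes, 0.010 and 0.010 with the line as a block). Oxidative phosphorylation genes ranked lower, with 41 of 43 below 0, a median of -0.08 and none called (adjusted p = 2.2e-06, adjusted p = 0.75 with an estimated correlation). They rise along the first component (median correlation 0.556), where naive specific line 3 and naive unspecific line 2 lay far out at 54.55 and 57.73. Without the 3 far libraries 41 of 43 lay below 0 (median -0.07; 2.8e-05, 0.62 with an estimated correlation). Cytosolic ribosomal proteins also ranked lower, with 57 of 65 below 0 and a median of -0.03 (adjusted p = 0.0024, adjusted p = 0.88 with an estimated correlation). Hemocyte-linked genes had 10 of 11 below 0 and passed only with the line as a block (adjusted p = 0.073 without, 0.041 with it) or without the 3 libraries far out on the first component (0.027), and not with an estimated correlation (adjusted p = 0.77). The phenoloxidase and melanin list did not pass (adjusted p = 0.56), but its members moved apart. Adjusted over the list alone, Ddc at 0.78 and Y-e3 at 0.51 rose (adjusted p = 0.11 and 0.052 over all genes, 0.0016 and 0.0027 with the line as a block) and Tyr2, a phenoloxidase, fell by 1.14 (adjusted p = 0.098 over all genes, 0.0058 with the line as a block). No other list passed in this comparison. The numbers above 0 were 3 of 5 recognition proteins, 17 of 28 Toll and IMD genes, 4 of 9 serpins and clip proteases, 5 of 19 reactive oxygen genes, 17 of 25 wound and stress genes, 5 of 13 heat shock proteins, 14 of 32 detoxification genes, 19 of 52 cuticle and chitin genes, 10 of 19 digestive enzymes, 18 of 32 chemosensory proteins, 2 of 22 muscle genes, 22 of 44 neural genes, 16 of 40 moulting and juvenile hormone genes, 12 of 25 testis and germ line genes and 18 of 33 chromatin modifiers. Lyz, the only lysozyme on its list, stood at 0.33 ± 0.21 (adjusted p = 0.75). Genes with only a LOC identifier can be missing from all these lists.

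Priming with Bt1 raised 126 genes and lowered 1, averaged over regimes. Tsf1 rose by 4.11 ± 0.26 (adjusted p = 5.2e-17, 15 of 15 lines), DptB by 2.92 ± 0.41 (adjusted p = 1.4e-06, 15 of 15), Def by 2.13 ± 0.55 (adjusted p = 0.033, 15 of 15) and cec2 by 1.91 ± 0.33 (adjusted p = 1.1e-04, 15 of 15). Ddc, dopa decarboxylase, rose by 0.88 and the yellow family gene Y-e3 by 0.62, while the phenoloxidase and melanin list that holds both did not pass (2 of 22 called, 14 above 0; camera adjusted p = 0.30). Both ferritin subunits rose slightly, Fer1HCH by 0.21 and Fer2LCH by 0.21. Serpin5 rose by 0.72, Gnbp2 by 0.61, Indy by 0.75, sPLA2C by 0.80, Csp10 by 0.70, Idgf4 by 0.54, Idgf2 by 0.45 and the cytochrome P450 Cyp4q3 by 0.63. Idgf2 and Ddc overlap another gene in position, by 58 and 3 bases. Iron and storage proteins ranked higher with 9 of 14 above 0 and 3 called (camera adjusted p = 2.1e-05), and held with an estimated correlation (adjusted p = 0.031). The list holds Tsf1 and was not tested without it. Wound and stress genes ranked higher with 20 of 25 above 0 and none called (adjusted p = 0.0091, adjusted p = 0.68 with an estimated correlation). All 65 ribosomal protein genes lay below 0, with a median of -0.05 and none called (adjusted p = 1.5e-06, adjusted p = 0.87 with an estimated correlation). Oxidative phosphorylation passed only with the line as a block (33 of 43 below 0; adjusted p = 0.16 without, 0.024 with it) and not with an estimated correlation (adjusted p = 0.92). The block by line gave 244 genes (217 higher, 27 lower), including all 127.

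Priming with Pf raised 80 genes and lowered 4, averaged over regimes. Tsf1 rose by 3.77 ± 0.26 (adjusted p = 6.1e-16, 15 of 15 lines), DptB by 3.71 ± 0.43 (adjusted p = 1.2e-08, 15 of 15), Def by 3.19 ± 0.52 (adjusted p = 3.6e-05, 15 of 15) and cec2 by 1.86 ± 0.33 (adjusted p = 2.0e-04, 14 of 15). Serpin5 rose by 0.63, Gnbp2 by 0.53, Indy by 0.69 and sPLA2C by 0.70. No gene with a symbol fell. Iron and storage proteins ranked higher with 11 of 14 above 0 and 1 called (camera adjusted p = 4.1e-04, adjusted p = 0.13 with an estimated correlation), and the phenoloxidase and melanin list with 15 of 22 above 0 and none called (adjusted p = 0.041, adjusted p = 0.44 with an estimated correlation). All 65 ribosomal protein genes lay below 0 (median -0.06; adjusted p = 8.3e-13, adjusted p = 0.52 with an estimated correlation), as did 42 of 43 oxidative phosphorylation genes (median -0.08; adjusted p = 3.1e-08, adjusted p = 0.61 with an estimated correlation). Without the 3 far libraries, 2 of them naive, 41 of 43 oxidative phosphorylation genes lay below 0 (median -0.08; 5.1e-07, 0.72 with an estimated correlation). With the line as a block 161 genes passed (130 higher, 31 lower), including all 84, and recognition proteins (adjusted p = 0.032, higher), reactive oxygen genes (0.023, lower) and muscle genes (0.037, lower) passed as lists, where they had not without it (0.087, 0.059 and 0.054) or with an estimated correlation (0.32, 0.44 and 0.90). The melanin list missed the threshold without the 3 far libraries (0.072).

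**Figure D2:**
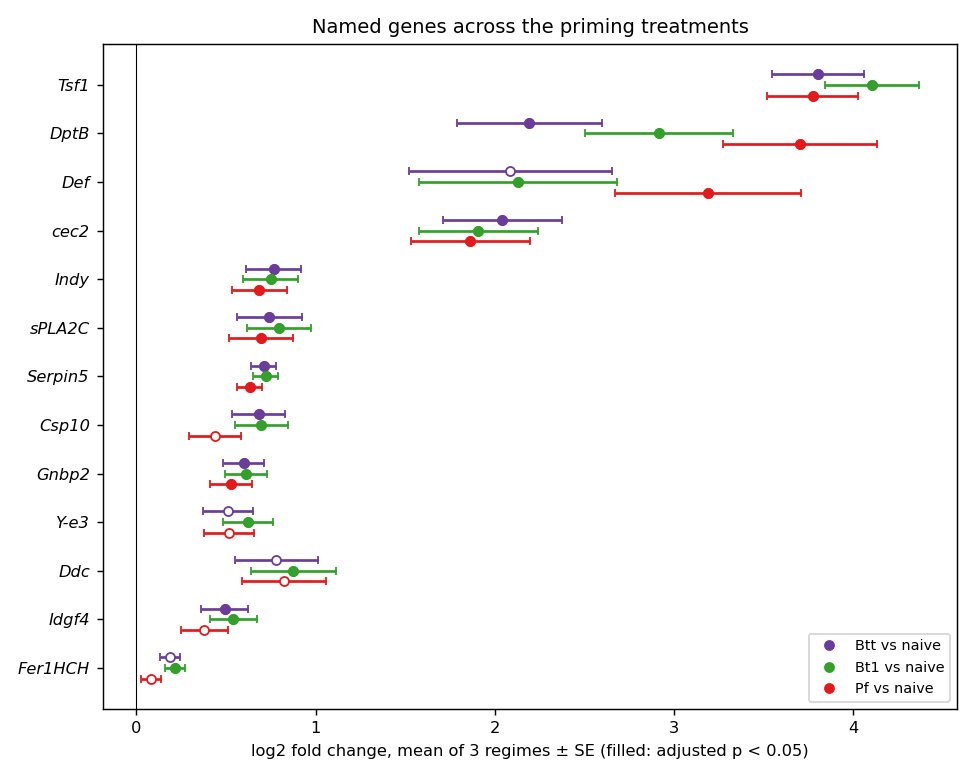
Log2 fold change against naive larvae with its SE, averaged over the 3 regimes, for 13 named genes and the 3 bacteria. Filled points passed an adjusted p of 0.05 and open points did not. Tsf1 lies at 3.80, 4.11 and 3.77, and DptB at 2.19, 2.92 and 3.71, after Btt, Bt1 and Pf.

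The sets of genes raised by the 3 bacteria overlapped. Of 140 genes raised by any of them, 74 rose with all 3, 14 with Btt alone, 24 with Bt1 alone and 0 with Pf alone; whether a gene responds to 1 bacterium only was not tested by these counts. Of the 140, 26 had a symbol. The 7 with a symbol among the 74 were Tsf1, DptB, cec2, Serpin5, Gnbp2, Indy and sPLA2C. Btt and Bt1 shared 96 raised genes, Btt and Pf 74, and Bt1 and Pf 80, where independent lists would share 1.21, 0.768 and 0.880. All 3 comparisons used the same naive libraries. All 60 libraries, naive ones included, were simulated 40 times from a common mean per gene, with no change by treatment. The simulated comparisons again shared their naive libraries, while the real naive libraries themselves were not used. The simulated libraries carried no differences between lines and the fits had no line term, so the pairing of primed and naive libraries by line is not part of the simulated values. In simulation the mean overlap was 0, and the correlation of log2 fold changes across genes, which are not independent replicates, was 0.504, 0.503 and 0.504. The observed correlations were 0.655, 0.683 and 0.648. The covariances were 0.0324, 0.0355 and 0.0322 against 0.0170, 0.0169 and 0.0169 in simulation, a difference of 0.0154, 0.0186 and 0.0153. With the naive libraries split between the comparisons, 42.5, 36 and 41 raised genes were shared on average, against 0.293, 0.258 and 0.321 for independent lists, with correlations of 0.275, 0.313 and 0.278. The primed libraries of both comparisons still came from the same lines, so differences between lines also enter these correlations.

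In specific immunity lines alone, 50 genes rose and none fell after Btt, 64 rose after Bt1, and 40 rose and 1 fell after Pf. Tsf1 rose by 3.44 ± 0.35, 3.77 ± 0.36 and 3.17 ± 0.35 (adjusted p = 4.0e-09, 2.8e-10 and 3.6e-08, 6 of 6 lines each). The peptide cec2 rose by 2.00, 1.98 and 1.98 (adjusted p = 0.032, 0.030 and 0.045). DptB rose after Bt1 by 2.68 and after Pf by 2.76 (adjusted p = 0.0059 and 0.0062) and stood at 2.12 after Btt (adjusted p = 0.092, 1.7e-04 with the line as a block). Serpin5 rose by 0.78, 0.75 and 0.66 in the same order, and Indy rose after Btt by 0.96 and after Bt1 by 0.97. Def stood at 1.51, 1.63 and 2.22 (adjusted p = 0.79, 0.97 and 0.21), and passed after Pf with the line as a block (6.9e-04). Muscle genes lay below 0 in 22 of 22 after Btt, 22 of 22 after Bt1 and 21 of 22 after Pf, with medians of -0.17, -0.11 and -0.11 and none called (camera adjusted p = 2.3e-05, 0.0025 and 0.0029; 0.70, 0.76 and 0.74 with an estimated correlation). Oxidative phosphorylation genes lay below 0 in 42 of 43 after Btt (median -0.15; adjusted p = 1.5e-12; 0.59 with an estimated correlation). These genes rose along the first component (median correlation 0.556), where naive specific line 3 lay far out at 54.55. Without the 3 far libraries 42 of 43 still lay below 0 (median -0.13; 2.6e-10, 0.63 with an estimated correlation). Blocked by line, 105, 105 and 76 genes passed. The Pf count was 19 without specific line 1 and 24 without specific line 6.

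In unspecific immunity lines alone, 67 genes rose and 6 fell after Btt, 60 rose and 2 fell after Bt1, and 31 rose after Pf. Tsf1 rose by 3.66 ± 0.36, 4.08 ± 0.36 and 3.74 ± 0.36 (adjusted p = 3.4e-10, 3.1e-11 and 3.6e-10, 6 of 6 lines each). After Btt, Serpin5 rose by 0.73, Indy by 1.10 and Idgf4 by 0.80, and Ran fell by 0.41, Gar1, of the small nucleolar ribonucleoproteins, by 0.42 and the helicase mle by 0.32. After Bt1, DptB rose by 2.48, Serpin5 by 0.72 and Gnbp2 by 0.69, and MBD-like, of the methyl-CpG binding family, fell by 0.38; after Pf, DptB rose by 2.86 and Serpin5 by 0.50. Gar1 and MBD-like overlap a gene on the other strand. The peptides that missed the threshold passed with the line as a block for cec2 (1.91, 1.93 and 1.90; blocked adjusted p = 0.0050, 0.0030 and 0.0052), for DptB after Btt (2.02; 3.6e-04) and for Def after Pf (2.23; 0.0019), but not for Def after Btt (1.79; 0.051) or Bt1 (1.26; 0.30). Iron and storage proteins ranked higher after each bacterium, with 10, 10 and 11 of 14 above 0 (camera adjusted p = 1.8e-04, 2.5e-05 and 9.2e-06; 0.10, 0.033 and 0.026 with an estimated correlation). Tsf1 is a member of this list, which was not tested without it. All 65 ribosomal protein genes lay below 0 after Bt1 and Pf and 63 of 65 after Btt (adjusted p = 8.5e-13, 9.7e-14 and 1.5e-07; 0.76, 0.59 and 0.63 with an estimated correlation). Hemocyte-linked genes lay above 0 in 9 of 11 after Pf (median 0.27; adjusted p = 0.011, 0.59 with an estimated correlation). They fell along the first component, where naive unspecific line 2 lay far out, and without the 3 far libraries 10 of 11 lay above 0 (median 0.30; 0.015, 0.68 with an estimated correlation). Blocked counts were 430 (256 higher, 174 lower), 143 and 73. Fitted to only these groups, without the other regimes, they were 16, 19 and 12. The Btt count was 134 in DESeq2 and 35 without unspecific line 5.

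In control lines alone, 12 genes rose after Btt, 18 after Bt1 and 21 after Pf, and none fell. Tsf1 rose by 4.31 ± 0.52, 4.47 ± 0.52 and 4.41 ± 0.52 (adjusted p = 6.2e-07, 2.7e-07 and 1.9e-07, 3 of 3 lines each). DptB rose after Pf by 5.50 ± 0.95, from 2.42 ± 1.43 to 107.1 ± 85.5 CPM (adjusted p = 6.7e-04, 3 of 3), and stood at 2.44 after Btt and 3.59 after Bt1 (adjusted p = 0.88 and 0.11; 0.024 and 0.0011 with the line as a block). Serpin5 rose after Bt1 by 0.69 and after Pf by 0.74. The peptide cec2 stood at 2.23, 1.81 and 1.71 (adjusted p = 0.55, 1.0 and 1.0; 0.021, 0.11 and 0.13 with the line as a block). Hemocyte-linked genes all lay below 0 after Btt (11 of 11, median -0.62; 0 called over all genes and 3 adjusted over the list alone; camera adjusted p = 5.4e-09, adjusted p = 0.20 with an estimated correlation). The same genes fell along the first component (median correlation -0.596), where lines 1, 2 and 3 stood at -2.87, -13.33 and -2.11 in naive larvae and at 13.87, 46.18 and -7.09 after Btt. Whether the list difference goes beyond that component was not tested. After Bt1, 9 of 11 hemocyte-linked genes lay below 0 (camera adjusted p = 0.0090, adjusted p = 0.96 with an estimated correlation). Counts in these 3 lines moved with single lines: without control lines 1, 2 and 3 in turn they were 1, 1 and 6 for Btt, 9, 2 and 7 for Bt1, and 10, 5 and 9 for Pf, and the Btt count was 19 without unspecific line 1. With the line as a block they were 50, 50 and 46, and in DESeq2 27, 29 and 36. Fitted to only these groups, the Btt count was 26 (16 higher, 10 lower) and the Bt1 count 5.

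The lists of raised genes were shared between regimes, which have no libraries in common. All 12 genes raised by Btt and all 18 raised by Bt1 in control lines had also risen in specific and in unspecific lines, and 17 of the 21 raised by Pf had done so in each of the others. Specific and unspecific lines shared 41 of 50 and 67 genes after Btt, 51 of 64 and 60 after Bt1, and 29 of 40 and 31 after Pf, where independent lists would share 0.292, 0.335 and 0.108. Every gene called in either of these 2 regimes had the same direction in the other (82 of 82, 75 of 75 and 43 of 43). Between unspecific and control lines this held for 64 of 73 genes after Btt, 62 of 62 after Bt1 and 35 of 35 after Pf, and between specific and control lines for 50 of 50, 63 of 64 and 45 of 45. Across all genes, which are not independent replicates, the correlation of log2 fold changes after Btt was 0.0302 between specific and control lines, 0.0256 between unspecific and control lines and 0.540 between specific and unspecific lines. In the same order it was 0.242, 0.319 and 0.369 after Bt1 and 0.30, 0.304 and 0.507 after Pf. On the first component naive specific line 3 and naive unspecific line 2 lay far out at 54.55 and 57.73. Control line 2 after Btt stood at 46.18. The correlations were not computed without these libraries, so they do not show that control lines responded differently to Btt.

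**Figure D3:**
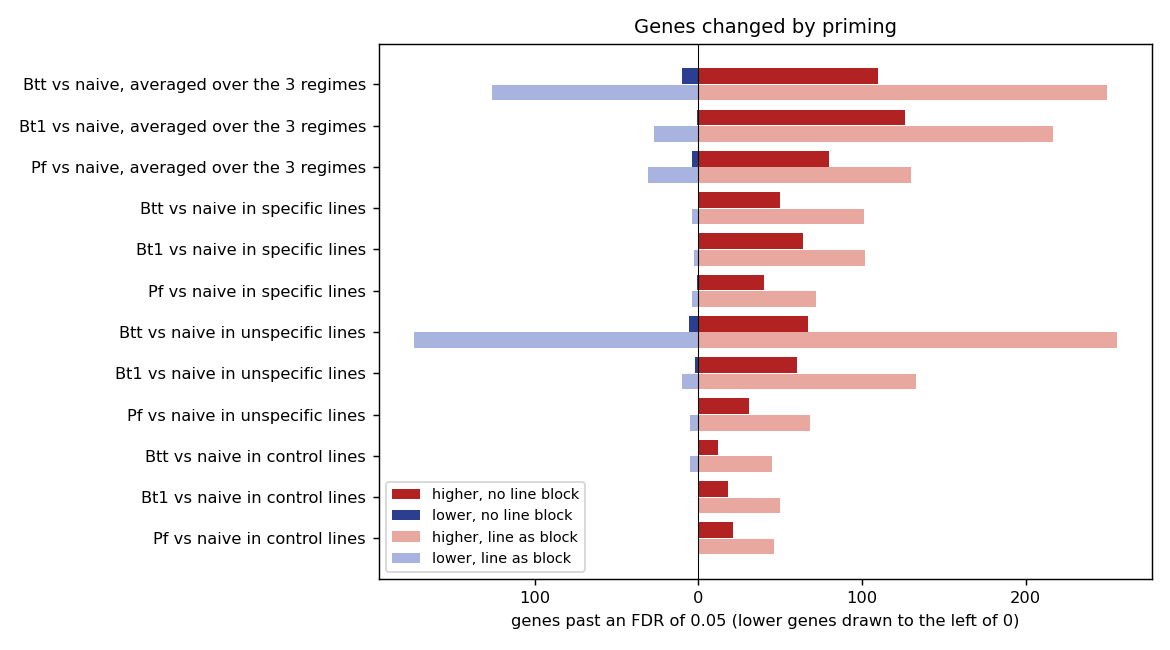
Genes past an FDR of 0.05 in each comparison of primed with naive larvae, raised genes to the right of 0 and lowered genes to the left. Dark bars are fits without and pale bars fits with the line as a block, and Btt in unspecific lines moved most, from 73 to 430 genes.

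The bacteria were compared directly to see how specific the response is. Pf gave more of certain transcripts than Btt. LOC103314753 was lower after Btt than after Pf by 2.19 ± 0.27 on the log2 scale (4.52 ± 2.12 against 19.6 ± 19.4 CPM; adjusted p = 1.6e-06, 15 of 15 lines), its neighbour LOC103314751 by 2.14 ± 0.34 (adjusted p = 3.8e-04, 15 of 15) and the noncoding RNA LOC107398713 by 1.48 ± 0.29 (adjusted p = 0.016, 13 of 15). LOC103314753 was also lower after Bt1 than after Pf, by 1.45 ± 0.26 (adjusted p = 0.011, 15 of 15). No other gene passed in either comparison, and these 3 were chosen after their values were seen. DptB was lower after Btt than after Pf by 1.51 ± 0.37 (12 of 15 lines; adjusted p = 0.20, 4.4e-04 with the line as a block), and Def by 1.10 ± 0.42 (12 of 15; adjusted p = 0.63, 0.031 with the block). For cec2 the same difference was 0.18 ± 0.30 and its block gave an adjusted p of 0.93. With the line as a block 26 genes differed between Btt and Pf (7 higher and 19 lower in Btt) and 2 between Bt1 and Pf. DESeq2 called 8 and 2, and fits to only the groups compared 7 and 0. The count between Bt1 and Pf was 0 without control line 1 or 3, specific line 4 or unspecific line 4, and 2 without unspecific line 6. Between Btt and Bt1, edgeR called 0 genes with or without the block, at 545 with an unadjusted p under 0.05, and DESeq2 called 0. Hemocyte-linked genes lay lower in 10 of 11 after Btt than after Pf (median -0.17; camera adjusted p = 0.0013, 1.0 with an estimated correlation) and in 10 of 11 after Bt1 than after Pf (median -0.12; 0.042, 0.10 without the 3 far libraries, 0.76 with an estimated correlation). Within regimes the list passed between Btt and Pf in control lines (1.3e-05, 0.33 with an estimated correlation) and not in specific (0.37) or unspecific lines (0.71). It falls along the first component (median correlation -0.596), where control line 2 after Btt stood at 46.18. All 43 oxidative phosphorylation genes lay higher after Bt1 than after Pf (adjusted p = 0.0016; 0.82 with an estimated correlation, given as the last value from here on), and 38 of 43 lay lower after Btt than after Bt1 (0.0016; 0.92). Within regimes, Btt lay below Bt1 in specific (6.7e-12, 0.74) and unspecific lines (1.1e-06, 0.72) but above it in control lines (0.0037, 0.96). Bt1 lay above Pf in unspecific (0.0087, 0.81) and control lines (1.1e-05, 0.83), and the list did not pass in specific lines (lower, 0.87, 0.99). This list rises along the first component (median correlation 0.556), where unspecific line 6 after Bt1 lay far out at 70.9. Ribosomal proteins lay higher in 52 of 65 after Btt than after Pf (0.0013; 1.0), and detoxification genes in 22 of 32 after Bt1 than after Pf (0.042, 0.058 without the 3 far libraries; 0.76). Within regimes the ribosomal list passed between Btt and Pf in control lines only (higher, 3.2e-10, 0.47). It did not pass in unspecific (higher, 0.79, 0.98) or specific lines (lower, 0.42, 0.999).

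Within each regime, any difference among the 3 bacteria was tested jointly. In control lines LOC103314753 alone passed in edgeR (adjusted p = 0.0011), and 5 genes passed with the line as a block, DptB among them (0.0025). The count of 1 was 2 in DESeq2, 0 when only these groups were fitted, 0 without control line 3, 2 without unspecific line 1 and 2 without unspecific line 5. In specific lines edgeR called 0 genes (147 at an unadjusted p under 0.05, DESeq2 0; 1 without a filter), and in unspecific lines 0 (741, DESeq2 0). Def, cec2 and DptB had adjusted p-values of 0.95 or more in all 3 joint tests without the block. Among pairs of bacteria within unspecific lines, 92 genes differed between Btt and Pf with the line as a block (31 higher, 61 lower in Btt) and 0 without it, at an unadjusted count of 956. Within control lines 2 genes differed between Btt and Pf without the block and 5 with it, all lower after Btt, and 0 and 1 between Bt1 and Pf. The other 6 pairs within a regime gave 0 both ways.

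Selection regimes were compared by the sum of the 4 libraries of each line, and no gene passed. In edgeR, specific against control lines gave 0 genes (378 at an unadjusted p under 0.05), unspecific against control lines 0 (902) and specific against unspecific lines 0 (1467). DESeq2 called 25, 53 and 123. For the same pairs of regimes, limma-voom with the line as a random effect called 36, 45 and 101. That fit used the unsummed libraries, so both its unit and its model differ from those of the sums. Without unspecific line 3 edgeR called 3 genes between unspecific and control lines and 38 between specific and unspecific lines, and without control line 3 it called 1 in the last. Against control lines, specific lines had 275.2 CPM of Rel, the transcription factor of the IMD pathway, against 203.5 CPM (log2 0.44 ± 0.12; adjusted p = 0.83, higher in 6 of 6 lines), and Dredd, a caspase of that pathway, stood at 0.22 ± 0.06 (adjusted p = 0.68, 6 of 6). The chitinase gene Cht13 stood at -1.09 in specific and -1.36 in unspecific lines against control lines (adjusted p = 0.83 and 0.21, lower in 6 of 6 lines each). Tyr1 and Tyr2, phenoloxidases, stood at -1.31 and -1.51 in unspecific against control lines and at 1.30 and 1.55 in specific against unspecific lines (adjusted p = 0.33, 0.37, 0.25 and 0.25, 6 of 6 lines each). Summed DptB was 47.2 ± 20.1 CPM in specific, 29.8 ± 18.2 in unspecific and 37.8 ± 27.9 in control lines, and the 3 peptides had adjusted p-values from 0.43 to 1.0.

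Hemocyte-linked genes passed as a list in these sums with the preset correlation only. All 11 lay lower in unspecific than in control lines (median -0.39; camera adjusted p = 5.6e-07, adjusted p = 0.46 with an estimated correlation), among them the clotting factor Hml at -1.14, the basement membrane collagen Col4a1 at -0.44 and the laminin LanA at -0.55. All 11 lay higher in specific than in unspecific lines (median 0.40; 4.2e-08, 0.52 with an estimated correlation; 6 adjusted over the list alone). The list falls along the first component (median correlation -0.596), where unspecific line 2 in naive larvae and line 6 after Bt1 lay far out at 57.73 and 70.9. With the 3 far libraries left out of the sums, all 11 still lay lower and higher (medians -0.38 and 0.40; 4.7e-07 and 1.8e-08; 0.53 and 0.46 with an estimated correlation). Whether the difference goes beyond that component was not tested. Neural genes lay higher in unspecific than in control lines in 40 of 44 (median 0.27; adjusted p = 4.4e-06, 0.78 with an estimated correlation) and lower in specific than in unspecific lines in 39 of 44 (2.7e-04; 0.76, the last value in each bracket from here on being that with an estimated correlation). They rise along the second component (median correlation 0.640), for which the line accounted for an adjusted share of 0.731 of the variance. Specific lines had lower ribosomal protein genes than control (63 of 65; 1.3e-17; 0.67) and unspecific lines (65 of 65; 5.8e-22; 0.52). Oxidative phosphorylation genes lay lower in 42 of 43 and 43 of 43 in the same comparisons (2.0e-16 and 7.2e-12; 0.67 and 0.71), with medians of -0.15 in both. They rise along the first component (median correlation 0.556). With the 3 far libraries left out of the sums, 42 and 41 of 43 still lay lower (8.1e-15 and 9.3e-11, 0.74 and 0.66). Muscle genes lay lower in specific than control lines in 20 of 22 (0.0075; 0.67). Cuticle genes lay lower in unspecific than control lines in 38 of 54 (0.0019; 0.46) and higher in specific than unspecific lines in 40 of 54 (8.9e-04; 0.59), where wound and stress genes also lay higher in 19 of 25 (0.0032; 0.52). Iron and storage proteins lay lower in unspecific than control lines in 13 of 14 (0.018; 0.46).

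In naive larvae alone, 24 genes were lower and 4 higher in unspecific than in control lines. Tyr1 was lower by 1.86 ± 0.44 on the log2 scale (32.1 ± 20.4 CPM, n = 6 lines, against 116.3 ± 31.96, n = 3; adjusted p = 0.049), the lipocalin Karl by 1.59 ± 0.36 (adjusted p = 0.047) and Col4a1 by 1.06 ± 0.25 (417.7 ± 133 against 868.6 ± 57.8 CPM; adjusted p = 0.047), each in 6 of 6 lines. The initiation factor subunit eIF2Bgamma was higher by 0.33 ± 0.07 (adjusted p = 0.039, 6 of 6). Karl overlaps another gene on its strand. All 11 hemocyte-linked genes lay lower (median -0.80; 1 called over all genes and 9 adjusted over the list alone; camera adjusted p = 2.5e-11, adjusted p = 0.083 with an estimated correlation). These genes also fell along the first component of all libraries (median correlation with the scores -0.596), where naive unspecific line 2 lay far out at 57.73. Without the 3 far libraries all 11 still lay lower (median -0.74; 1.9e-10, 0.13 with an estimated correlation), while Tyr1, Karl and Col4a1 missed the threshold (adjusted p = 0.052, 0.052 and 0.063). They missed it without a filter as well (0.056, 0.054 and 0.054). Whether the rest of the list difference follows that component was not tested. The count was 43 in DESeq2, 9 without a filter, 0 when only these groups were fitted and 18 without the 3 libraries far out on the first component. It was 142 without unspecific line 3, 0 without control line 1 or 2 or unspecific line 1 or 5, 1 without specific line 3 or 4, 3 without specific line 1 or 2, 8 without unspecific line 6, 9 without unspecific line 4 or specific line 6, 10 without specific line 5 and 11 without control line 3.

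Specific and unspecific lines differed in 1 gene in naive larvae, LOC658237, higher by 0.51 in specific lines (adjusted p = 0.043, 6 of 6 lines), chosen after its values were seen. That count was 16 in DESeq2, 0 without a filter, 0 when only these groups were fitted, 0 without the 3 libraries far out on the first component and 113 without unspecific line 3. It was 2 without unspecific line 6, and 0 without control line 1 or 2, any 1 of the 6 specific lines, or unspecific line 1, 2 or 5. All 65 ribosomal protein genes lay lower in specific lines (median -0.17; 27 adjusted over the list alone; camera adjusted p = 7.1e-25, 0.32 with an estimated correlation) and all 11 hemocyte-linked genes higher (median 0.49; 7 adjusted over the list alone; 9.8e-09, 0.27 with an estimated correlation). Hemocyte-linked genes fall along the first component (median correlation -0.596), where naive specific line 3 and naive unspecific line 2 lay far out at 54.55 and 57.73. Whether their difference goes beyond that component was not tested. Between naive specific and control lines edgeR called 0 genes (386 at an unadjusted p under 0.05, DESeq2 0). DptB was 10.2 ± 3.33 CPM in naive specific, 6.61 ± 4.77 in unspecific and 2.42 ± 1.43 in control lines, at a log2 difference of 2.11 ± 0.83 between specific and control lines (adjusted p = 1.0; above the control mean in 6 of 6 lines).

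Whether regimes differ in their response to priming was tested on the interaction terms, and no gene passed. In edgeR, specific against control lines gave 0 genes (123 at an unadjusted p under 0.05), unspecific against control lines 0 (203) and specific against unspecific lines 0 (131), and DESeq2 called 0 in each. The line as a block gave 0 in each. Without the block, the unadjusted counts lie below the share of 0.05 of genes that would pass if none differed. That fit leaves differences between lines in the error of these terms. The largest differences of an antimicrobial peptide above the floor were in the response of DptB to Pf, which was smaller than in control lines by 2.74 ± 1.03 in specific and 2.64 ± 1.04 in unspecific lines (adjusted p = 1.0 in both). DptB had adjusted p-values of 1.0, 1.0 and 1.0 in these joint tests, and 0.88, 0.77 and 1.0 with the line as a block.

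The first principal component of the 60 libraries held 21.1% of the variance and the second 8.65%. The adjusted share of the second component's variance that the line accounted for was 0.731, against 0.371 for the regime and -0.0174 for the priming treatment. For the first component these were 0.320, -0.00811 and 0.0361. Within regimes, 3016 of 11208 genes (26.9%) differed among specific lines, 4935 of 11218 (44.0%) among unspecific lines and 577 of 10976 (5.26%) among the 3 control lines at an adjusted p under 0.05 in edgeR, with the treatment in the model. The control test had 12 libraries of 3 lines, against 24 of 6 lines in each other regime. These shares therefore differ in power and do not show that control lines were more alike. Libraries of the same line correlated at 0.316 in control and 0.269 in specific lines.

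**Figure D4:**
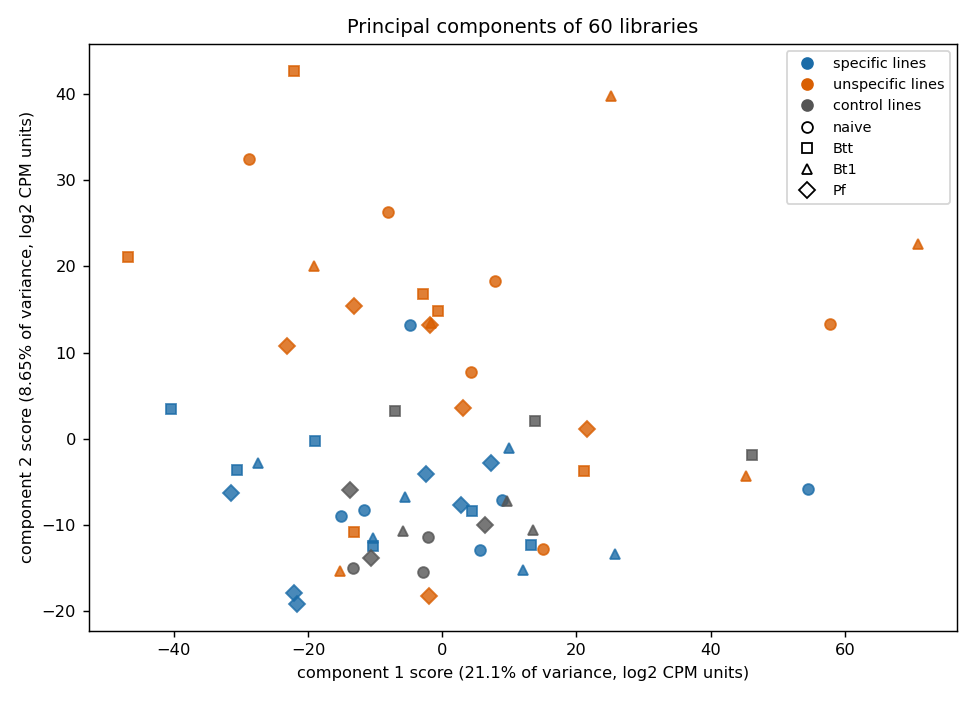
Scores of the 60 libraries on the first and second principal component of log2 CPM, with 21.1% and 8.65% of the variance. Each point is a library, coloured by selection regime and shaped by priming treatment, and the farthest along the first component is unspecific line 6 after Bt1 at 70.9.

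Over all comparisons 88 of 420 list tests passed in camera with the preset correlation, and 3 held with an estimated one: iron and storage proteins after Bt1 averaged over regimes and after Bt1 and Pf in unspecific lines. Since that list holds Tsf1 and was not tested without it, these 3 results do not show a rise of the list as a whole. In fry, 11 list tests passed in one direction and 8 in either direction. Among the list tests of primed larvae that could be blocked by line, 57 passed without and 56 with the block, 47 passed in both and 0 of these changed direction.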

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

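The tests named here followed fixed rules, and only the fit without far libraries was chosen after seeing the data. The highest and lowest library of each of the 8 groups of 6 were compared with the nearest other library for 7 measures: total count, genes detected, the percent of counts in the top 10 genes, DptB, Def, cec2 and Tsf1, and 7 of 56 such tests passed Dixon's limit. Chance flags about 1 in 20 groups of normally distributed values. The values were tested unlogged, and counts near the floor such as those of Def are skewed, so this share need not hold here. In total count, a library far from the others of its group was specific naive line 5 at 14.1 M (next 10.6) and unspecific line 1 after Btt at 14.2 M (next 10.6). In Def the far libraries were specific naive line 5 at 3.02 CPM (next 0.785), unspecific naive line 1 at 2.86 CPM (next 0.236) and unspecific line 1 after Bt1 at 4.47 CPM (next 1.04). In cec2 it was unspecific line 3 after Btt at 9.23 CPM (next 3.78), and in Tsf1 unspecific line 3 after Pf at 2860 CPM (next 1520). No cause was tested for these single libraries.

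Responses of gene lists to priming were compared between regimes by interaction terms in camera, and differences passed with the preset correlation only. With the preset correlation 30 of 180 tests passed; with an estimated correlation 0 did (smallest adjusted p = 0.183). The response to Btt was higher in specific than in control lines for hemocyte-linked genes (adjusted p = 3.0e-06), cuticle genes (1.9e-04) and the melanin list (0.019), and lower for oxidative phosphorylation (6.3e-12), ribosomal proteins (3.8e-05) and muscle genes (0.046). In unspecific against control lines the response to Btt was higher for hemocyte-linked genes (1.7e-07), wound and stress genes (4.8e-04), cuticle genes (4.8e-04) and the melanin list (0.0050), and lower for oxidative phosphorylation (7.3e-10), ribosomal proteins (1.7e-07) and digestive enzymes (0.013). After Bt1, unspecific against control lines had a higher response of hemocyte-linked genes (2.3e-04) and a lower response of ribosomal proteins (9.1e-08). After Pf the hemocyte-linked response was higher than in control lines in specific (0.034) and in unspecific lines (4.4e-04). Some of these lists run along the first component, with a median correlation of -0.596 for hemocyte-linked genes, -0.329 for cuticle genes and 0.556 for oxidative phosphorylation. On it control line 2 after Btt stood at 46.18 and 2 naive libraries lay far out, specific line 3 at 54.55 and unspecific line 2 at 57.73. Without the 3 far libraries the hemocyte-linked response to Pf in specific against control lines missed the threshold (0.071), and the responses to Btt given above for these 3 lists still passed. Without them, lists passed that had not in the fit of all libraries: oxidative phosphorylation (0.040) and neural genes (0.0085) after Pf in specific against control lines, oxidative phosphorylation (0.042) and muscle genes (0.042) after Bt1 and ribosomal proteins after Pf (7.7e-04) in unspecific against control lines, and hemocyte-linked genes after Bt1 (0.0068) and neural genes after Pf (0.043) in specific against unspecific lines. Whether the differences go beyond that component was not tested.

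Between specific and unspecific lines the response to Btt was lower in specific lines for muscle (1.8e-06), wound and stress (2.6e-04), neural (0.0024) and chemosensory genes (0.0072), and higher for ribosomal proteins (0.048). After Bt1 it was lower for muscle genes (9.8e-06) and heat shock proteins (4.3e-04) and higher for ribosomal proteins (9.8e-06) and cuticle genes (5.6e-04). After Pf it was lower for muscle genes (0.015) and iron and storage proteins (0.036) and higher for ribosomal proteins (6.7e-05) and oxidative phosphorylation (1.6e-04). With the line as a block 6 more passed: detoxification (adjusted p = 0.080 without, 0.039 with it) and digestive enzymes (0.051, 0.039), both lower, after Btt in specific against control lines, and oxidative phosphorylation, higher (0.091, 0.022), and neural genes, lower (0.091, 0.022), after Pf there. In specific against unspecific lines they were serpins after Btt, higher (0.13, 0.033), and detoxification after Bt1, lower (0.062, 0.015). Each of the lists that passed without it was singled out because a test of the difference between regimes passed with the preset correlation.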

How the results depend on the processing

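The alternative that dropped 3 libraries far along the first component was the only one chosen after seeing the data. Of 73 calls of named genes, DESeq2 kept 73, the line as a block 69, no filter 63 and fits to only the groups compared 44, and none reversed in any alternative. With the replicate number as a block, which is the line for primed against naive larvae, the counts averaged over regimes were 376 for Btt, 244 for Bt1 and 161 for Pf against 120, 127 and 84. Within specific lines they were 105, 105 and 76, within unspecific lines 430, 143 and 73, and within control lines 50, 50 and 46, against 50, 64 and 41, 73, 62 and 31, and 12, 18 and 21. They were 26 for Btt against Pf, 2 for Bt1 against Pf and 5 for any difference in control lines. The block gained 38 calls of named genes and lost 4, all in naive unspecific against control lines. List tests that lost the call with it were serpins (adjusted p = 0.018 without, 0.058 with it), iron and storage (0.018, 0.058) and heat shock proteins (0.037, 0.12) after Btt, melanin after Bt1 (0.045, 0.095) and melanin (0.048, 0.073) and iron and storage (0.048, 0.16) after Pf in specific lines. So did melanin after Btt (0.046, 0.062) and cuticle after Bt1 (0.022, 0.072) in unspecific lines, and iron and storage after Bt1 (0.038, 0.30) and Pf (0.038, 0.12) in control lines. Beside those given with the results, it gained recognition after Btt (0.096, 0.033), oxidative phosphorylation after Bt1 (0.058, 0.0069) and reactive oxygen after Pf (0.12, 0.047) in unspecific lines, and digestive enzymes between Bt1 and Pf (0.061, 0.028). Between regimes the lines share a number only, and the block gave 1 gene for naive unspecific against control lines and 0 for naive specific against unspecific lines, where 28 and 1 had passed. Without the 3 far libraries and with the block, the counts were 392, 239 and 148 averaged, 95, 104 and 67 in specific, 528, 173 and 67 in unspecific and 55, 48 and 46 in control lines, 28 for Btt against Pf, 3 for Bt1 against Pf and 5 for any difference in control lines. Without them and without the block, naive unspecific against control lines gave 18 and naive specific against unspecific lines 0.

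DESeq2 gave 134 for Btt in unspecific lines, 27, 29 and 36 in control lines, 8 for Btt against Pf, 2 for Bt1 against Pf, 2 for any difference in control lines, 43 and 16 for naive unspecific against control and specific against unspecific lines, and 25, 53 and 123 for the sums. Fits to only the groups compared gave 16, 19 and 12 in unspecific lines, 26 and 5 for Btt and Bt1 in control lines, 7 and 0 for Btt and Bt1 against Pf, 0 for any difference in control lines and 0 and 0 for the naive comparisons of unspecific lines. No filter gave 1 for any difference in specific lines and 9 and 0 for the naive comparisons of unspecific lines. With the line as a random effect, limma-voom gave 36, 45 and 101 for the same pairs of regimes. It was fitted to the unsummed libraries, so it is not a second test of the sums. For list tests an estimated correlation gave 3, fry 11 and fry in either direction 8, against 88. The causes of these changes were not tested.

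With each line left out in turn, counts ran from 86 to 173, 87 to 138 and 64 to 97 averaged, from 35 to 56, 43 to 68 and 19 to 45 in specific lines, from 35 to 78, 42 to 66 and 21 to 40 in unspecific lines, and from 1 to 19, 2 to 26 and 5 to 30 in control lines for Btt, Bt1 and Pf. They ran from 2 to 4 for Btt against Pf, 0 to 2 for Bt1 against Pf, 0 to 2 for any difference in control lines, 0 to 142 and 0 to 113 for naive unspecific against control and specific against unspecific lines, and 0 to 3 and 0 to 38 for their sums. All others stayed at 0. At 8.49 to 14.22 M counts, 1 CPM is about 10 counts, which limits Def and cec2.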

Other observations

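The splits of libraries for the 27 comparisons, the depth tests on line differences and the random placement of genes were chosen only after the result was seen; the other tests were written before theirs. Genes without a symbol made up most of the raised genes, and some moved more than DptB, Def and cec2. LOC656629 rose by 3.03, 3.28 and 3.87 after Btt, Bt1 and Pf averaged over regimes, and LOC100141947 by 2.85, 3.35 and 4.27. LOC103314753 went from 0.954 ± 0.652 CPM in naive larvae to 4.52 ± 2.12, 7.20 ± 5.63 and 19.6 ± 19.4 CPM. These were chosen after their values were seen. Along the first component, hemocyte-linked genes had a median correlation of -0.596 with the scores and oxidative phosphorylation genes 0.556, and along the second neural genes had 0.640.

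Raised genes lay next to each other in the genome more often than randomly placed ones. Of 140 genes raised in any averaged comparison, 27 stood in 12 runs, with 15 adjacent pairs such as DptB with LOC100141947, Fer1HCH with Fer2LCH and Idgf2 with Idgf4. Random sets gave a mean of 1.70 and at most 8 pairs (permutation p = 1.0e-04, the smallest that 10000 sets allow), which excludes chance placement. Overlap in position was found in 20.0% of the pairs (3 of 15, 95% limits 4.33 to 48.1%), so it does not explain all pairs. In 100% of the 14 pairs with enough counts the ratio of neighbours varied over libraries beyond counting error. For these pairs, that excludes only that all counts of a gene were reads of its neighbour. Partial sharing of reads would pass this test as well. It stays open, since near-identical gene copies were not compared. No biological explanation was tested, since the design gives none.

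Lines of the same regime differed in many genes. Libraries were regrouped into other lines within each treatment, in quicker fits without robust estimation that called 3047, 4965 and 561 genes for the real lines, where the robust fits gave 3016, 4935 and 577. In specific, unspecific and control lines 1 of 100 groupings, the real one, reached the real count (highest other 12, 389 and 102), so chance is excluded. With total count as a covariate in the robust fits at least 91.8% of the genes were left in specific and unspecific lines, which argues against depth, and 23.6% in control lines, where depth stays open. Blocks of library numbers, not run in control lines, left at least 67.0%, which does not decide. The first component, used as a stand-in for differences in hatch or moult between pools, left at least 64.3% in all 3 regimes. Moulting and juvenile hormone genes did not follow that component (median correlation -0.0777, percentile 25.9 of expression-matched random lists), while cuticle genes did (-0.329). The stand-in may therefore not track hatch or moult, and it decides nothing about them. Drift and selection in the lines cannot be told apart by this design, and no biological explanation was tested.

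The spread along the first component was weighed against 3 technical causes. It showed no clear relation with the total count (Spearman rho = -0.245, 95% limits -0.488 to 0.0152, n = 60, p = 0.0586). It may still follow depth, since the limits reach -0.488, so depth stays open. It followed the share of counts in the top 10 genes (rho = 0.575, 0.36 to 0.734; permutation p = 1.0e-05, the smallest that 100000 permutations allow), so that explanation stays open; it also followed the number of genes detected (rho = -0.600, -0.753 to -0.391; permutation p = 1.0e-05), for which no explanation was weighed. Blocks of library numbers held 0.731% of its variance (95th percentile of permutations 12.6%; p = 0.938), which argues against the order of libraries. The limits and p-values above took each library as its own unit. Libraries of a line were alike, and the line accounted for an adjusted share of 0.320 of the variance of this component. The limits may therefore be too narrow and the p-values too small. No biological explanation was tested.

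Other splits were fitted to only the libraries compared and without robust estimation, so real counts differ slightly from those of the robust fits. For primed against naive larvae averaged over regimes, 1 of 100 splits, the real one, reached the real counts of 92, 110 and 82 (highest other 8, 1 and 7), and in specific lines likewise 58, 56 and 33 (highest other 6, 2 and 5), so chance can be excluded. In unspecific lines 2, 3 and 3 of 100 splits reached the real counts of 16, 20 and 12, with 388, 199 and 96 the highest, which points to a structure of the samples; among the 32 splits that part the pairs of each line, the highest other was 0 in each. In control lines there were too few splits, 10, of which 1 reached the real count. For Btt against Pf 1 of 100 reached the real 7 (highest other 2).

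Where the real split called 0 genes, every split reaches that count by construction, so these splits decide nothing about chance. The high counts of some other splits point to a structure of the samples. This held for 100 of 100 splits of Btt against Bt1 and Bt1 against Pf (highest other 278 and 29) and of the joint tests in specific, unspecific and control lines (423, 1689 and 119). For the sums it held for 84 of 84, 84 of 84 and 100 of 100 splits (highest other 22, 323 and 1 for specific against control, unspecific against control and specific against unspecific lines), for naive larvae for the same numbers (17, 26 and 89) and for the responses likewise (0, 1 and 0).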
